A study of Homo sapiens with 12 samples.

How the data were processed

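RNA from A2780, a human ovarian cancer cell line that is sensitive to cisplatin, and from A2780cis, its cisplatin-resistant derivative, was measured on 12 whole-genome Agilent arrays of 1 colour (Cy3), with 6 arrays per line. Per the labels' protocols, A2780cis was kept in medium with 1 uM cisplatin, and cells were harvested at 80% confluence. The series' design text describes independent experiments for each line. Replicates were therefore taken as separate cultures of a line, which the likeness of arrays on a slide, given below, leaves uncertain. Each array was assigned to its line and replicate number from its own label.

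Per the file headers and the submitters' processing notes, the authors' scanner images were quantified with Agilent Feature Extraction 10.5.1.1, which gave 1 processed signal intensity per spot, with background subtracted and no scaling between arrays. The deposited files of each array hold these intensities for 45015 spots, of which 1639 were control spots, together with median spot and local background intensities and a code for spots well above background. The 41000 probes had 1 spot each, except 264 that had 10. The authors also deposited a matrix of log2 values for the same arrays. Set against the scanner values, 41000 of its 41078 entries matched a probe, and the column medians lay between -0.116 and 0.201. Each column was correlated at 0.9999 or more with the log2 processed signal of its array less the array's 75th percentile and then each probe's median over the 12 arrays. Its scale was therefore log2, shifted by array and centred by probe. The 78 other entries were not used.

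The processed signal of each spot was put on the log2 scale, and the 75th percentile of its array was subtracted. Control spots and spots marked as non-uniform or as population outliers (35 to 72 per array) were left out, and spots of a probe were averaged. A probe was kept if it was well above background on at least 5 of the 6 arrays of at least 1 line. This kept 28561 of the 41000 probes (69.7%). The files give RefSeq and other sequence identifiers and no column of gene symbols. Symbols were therefore taken by matching identifiers, without versions, to the RefSeq gene table of assembly GRCh38.p14, which named 25398 probes. The array files name an older build, so no coordinates are given, and the table was used for symbols and for which genes neighbour each other. Each gene was represented by its brightest kept probe, and identifiers with no symbol were kept as features of their own. This gave 22127 genes, of which 13836 had a symbol. Among tested genes, 4989 had several kept probes. Probes for HLA genes and for metallothioneins lie in families of near-identical genes and may also bind their relatives.

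The lines were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, as A2780cis minus A2780 over all 12 arrays with no block, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. A count with a change of at least 2-fold was set beside it. For each of 34 gene lists, camera tested whether members ranked higher or lower than the other genes, with a preset correlation of 0.01 between genes and again with the correlation estimated for each list, and p values were adjusted over the lists. The lists covered DNA repair, platinum transport and detoxification, apoptosis, cell state, the cell cycle, interferon and antigen presentation, stress and metabolism, HOX genes, cancer-testis antigens, signalling pathways, 2 reference groups, and markers of 4 other cell types. Camera was also run on segments of 10 Mb with at least 10 tested genes. The source of gene symbols and the spot signal of the normexp alternative, given below, were settled after the files were seen to lack the planned columns. The lists, the alternatives and the other choices were fixed before the data were examined, except where a test is said to have been chosen later.

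Named genes were chosen by a rule fixed in the same way. It took the 12 genes that rose and the 12 that fell the most among genes with a symbol that were past the threshold, well above background on all 6 arrays of the higher line, not saturated, and of the same direction on each slide. It added up to 4 members of each list that passed, by size of change, and genes of known interest in platinum or drug resistance whatever their values. Some genes that the rule took are not reported here and were not replaced. Where a gene was not well above background on any array of a line, its change is given only as a lower bound. Where it was on some arrays of that line only, the change rests in part on values near background. The bound set the mean of the brighter line against the mean, over the arrays of the dimmer line, of the higher of the gene's own value and the lowest value of any probe well above background. Errors are the standard error (SE) of the limma fit, or the standard deviation (SD) over 6 arrays, as stated.

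Between 62.8% and 78.2% of probes were well above background on an array, the 75th percentile of signal ran from 293.9 to 772.6, and no spot was saturated. The number of arrays limits the precision. On simulated data with the spread of these arrays and 22108 genes, the fit of A2780cis against A2780 called 8% of 50 genes changed 1.5-fold, 32% of 50 changed 2-fold, 96% of 50 changed 4-fold and 94% of 50 changed 8-fold. It also called 7 unchanged genes, the planted list of 30 genes, and 1 of 33 unchanged lists. In 20 further simulations with nothing changed, 0 lists were called by camera and 1 gene by limma. The simulation held no difference between slides. In the data, the correlation estimated within a list ran from -0.1362 (fibroblast markers) to 0.7135 (metallothioneins). As given below, 82 of 100 divisions of the arrays gave at least 3 lists with the preset correlation. The 0 lists called in simulation therefore cannot show how often camera with the preset correlation calls unchanged lists in these data.

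The 12 arrays lay on 3 slides, each with 2 arrays of each line, and slide 1, with replicates 1 and 2 of both lines, was scanned on another day than the others. Slide was therefore tested as a block, within each slide, and by an interaction of slide and line. Because each slide held both lines equally, the slide block leaves each log2 fold change as it is and alters only its error. The 2 arrays of a line on a slide tended to be more alike than arrays of a line on different slides. The SD between 2 arrays was 0.172 to 0.561 on the same slide and 0.387 to 1.06 on different slides. Errors that take 6 arrays as independent may therefore be too small, and counts of called genes too high. Replicate numbers of the labels were shared by the lines, and arrays of the same number deviated together from their line means (correlation across genes 0.255 to 0.422 over the 6 pairs). Arrays of the same number also shared a slide, so this correlation cannot tell pairing by number from slide. The main fit used no pairing, and the fit with the replicate number as a block was run as an alternative.

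Other alternatives were normexp background correction with an offset of 50, quantile normalization, median scaling, the authors' values, no filter, a filter requiring all 12 arrays, marked spots kept, the mean of a gene's probes, an intensity trend with robust variance, array weights, each array left out, and segments of 20 and 5 Mb. The files used here hold no mean spot signal, so normexp was run on median spot signals. After the data were seen, 3 alternatives were added: the mean of the 2 arrays of a line on a slide (3 against 3), the 8 arrays without slide 1, and normexp with outlying local backgrounds replaced by the array's median.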

Results

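Gene expression was measured in 2 human ovarian cancer cell lines, cisplatin-sensitive A2780 and A2780cis, its derivative kept in cisplatin, with 6 arrays of each line. The comparison addresses which transcripts differ between this resistant and this sensitive line. Because only A2780cis was kept with the drug, resistance and drug exposure cannot be told apart in it. With a single line of each kind, resistance also cannot be told apart from any other difference between the lines. The p values measure the spread of arrays within these lines. Values below are log2 fold changes, A2780cis minus A2780, with the SE of the limma fit over 6 arrays per line, unless another quantity is named.

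The lines differed in 4263 of 22127 genes tested (19.3%), of which 2304 rose and 1959 fell in A2780cis. Of these, 1467 rose and 1239 fell by at least 2-fold. The count and its balance depended on the processing, with 1826 that rose and 2128 that fell under median scaling, and 537 and 556 with the 2 arrays of a line on a slide averaged, an alternative added after the data were seen. EPHX2 (soluble epoxide hydrolase), PPARG (a nuclear receptor of lipid metabolism) and INHBA (the activin A subunit) were among those that rose the most, and MEST, KANK4 and the transcription factor gene NKX2-1 among those that fell the most. Genes of HLA class I antigen presentation fell together and metallothioneins rose together by camera with the preset correlation, and neither list passed with an estimated correlation (adjusted p = 0.959 for both). The median over all genes was 0.03.

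Both A2780cis arrays of slide 1 stood apart from the other 4 A2780cis arrays. The first principal component held 48.7% of the variance and separated the lines, with A2780 from -95.6 to -57.5 and A2780cis of slides 2 and 3 from 95.6 to 117.1. The slide 1 A2780cis arrays lay between them, at 16.6 and 19.1, and apart from all others on the second component (28.7% of the variance), at 145.9 and 141.9. The line difference itself differed between slides in 6257 genes (limma F test of the interaction, adjusted p under 0.05), including 1670 of the called genes. The error of this test is the spread between the 2 arrays of a line on a slide. If these are not separate cultures, the interaction counts are too high. With slide as a block 7176 genes passed, and within slides 1, 2 and 3 the counts were 12580, 3393 and 5845. The count within slide 1 rests on 2 arrays per line that correlated at 0.9967 in A2780 and 0.9971 in A2780cis. Without slide 1, an alternative added after the data were seen, 5730 genes passed, 3513 of them among the 4263.

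**Figure D1:**
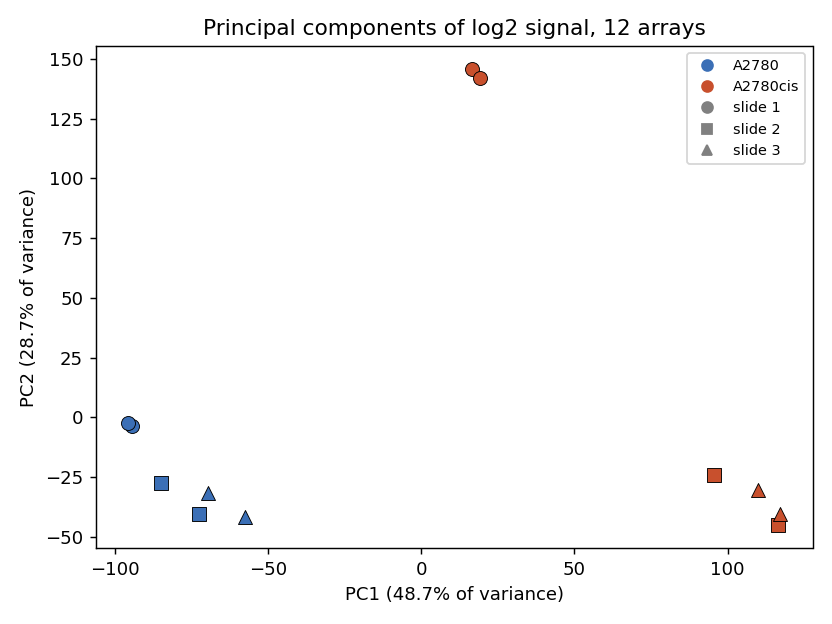
Principal components of log2 signal for the 12 arrays, with each point 1 array, colour for the line and shape for the slide. The axes give scores on the first (48.7% of variance) and second (28.7%) components, and the slide 1 A2780cis arrays sit at 145.9 and 141.9 on the second.

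Among genes that rose, EPHX2 was not well above background on any A2780 array and was at least 249.9-fold higher in A2780cis (limma adjusted p = 4.9e-12). PPARG was at least 109.7-fold higher, ECEL1 at least 96.3-fold, SHTN1 at least 58.6-fold, the complement regulator CD55 at least 56.3-fold and the fatty acid receptor CD36 at least 52.8-fold. The CD36 bound averages over slides, and its log2 signal was -5.92 and -5.49 on the slide 1 A2780cis arrays against at least 1.17 on the other 4. INHBA rose by 8.62 ± 1.53, with 3 of 6 A2780 arrays well above background. Its value was 3.06 on slide 1 and 11.43 and 11.36 on slides 2 and 3. GALNT14 (7.81 ± 1.37), the G protein subunit gene GNAI1 (7.78 ± 0.55), JAKMIP1 (7.54 ± 0.55), TMCO4 (7.46 ± 0.29) and the interferon lambda receptor gene IFNLR1 (7.11 ± 0.48) also rose. They were well above background on 5, 3, 4, 4 and 1 of the 6 A2780 arrays. GALNT14 was at 4.75 on slide 1 against 9.96 and 8.71 on slides 2 and 3, and GNAI1 at 5.48 against 9.04 and 8.82.

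Among genes that fell, MEST fell from a mean of 5.96 ± 0.16 (SD) in A2780 to -5.13 ± 1.18 in A2780cis, a change of -11.09 ± 0.44 (limma adjusted p = 2.23e-09). KANK4 (-10.39 ± 0.30), RGS1 (-9.94 ± 0.46) and the chemokine receptor gene CCR1 (-9.41 ± 0.53) also fell. Of the 6 A2780cis arrays, MEST and KANK4 were well above background on 3, and RGS1 and CCR1 on 2. NKX2-1, ARHGAP28, ANO3, the NADPH oxidase gene NOX4 and PRR16 were not well above background on any A2780cis array. They were at least 239-fold, 204-fold, 381-fold, 219-fold and 227-fold lower in A2780cis by their brightest probes. A second kept probe gave a smaller change for IFNLR1 (3.02), CCR1 (-5.13), NKX2-1 (-3.17), NOX4 (-6.89) and PRR16 (-6.11).

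**Figure D2:**
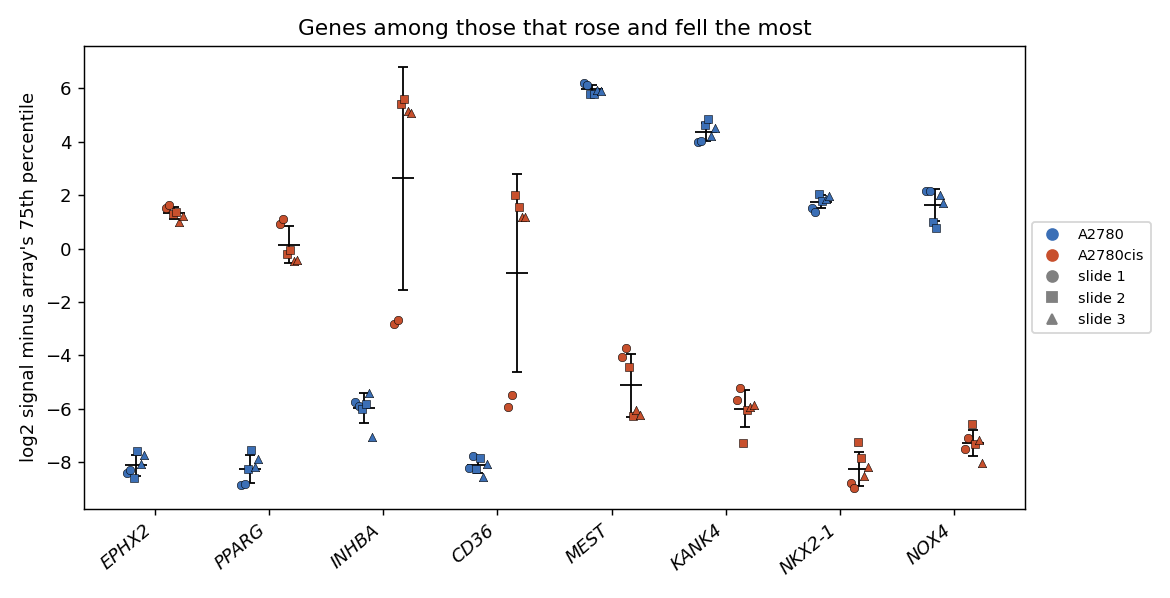
Log2 signal minus the array's 75th percentile for 4 genes that rose and 4 that fell, with each point 1 array, the long bar the mean of a line and the error bar its SD (n = 6). The slide 1 A2780cis arrays of INHBA and CD36 lie below those of slides 2 and 3.

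Copper transporters and drug pumps were named in advance for their reported part in platinum handling. ATP7A, a copper exporter, rose by 0.85 ± 0.18 but lost its call without slide 1 (0.64, adjusted p = 0.0602), while ATP7B was at -0.18 ± 0.21 (limma adjusted p = 0.642) and was opposite in sign on slide 1 (0.41) and on slides 2 and 3 (-0.39 and -0.55). The copper importer SLC31A1 was at -0.68 ± 0.24 and did not pass (limma adjusted p = 0.0674), but it passed with the replicate block (adjusted p = 0.0347). In platinum and copper transport, 2 of 12 genes rose and 1 fell (adjusted over the list alone, 2 and 2; camera adjusted p = 0.986). SLC47A1 rose (1.43 ± 0.38), and LRRC8D, a subunit of the volume-regulated anion channel, fell (-1.79 ± 0.29). Of 11 ABC drug transporters 0 passed limma, with 0 when adjusted over the list alone and 2 at an unadjusted p under 0.05 (camera adjusted p = 0.889). With slide as a block 0 rose and 3 fell. Among them ABCC2 was at 2.53 ± 1.26 (limma adjusted p = 0.199). Its log2 signal was 1.90 and 1.96 on the slide 1 A2780cis arrays, while the line difference was 0.05 on slide 2 and 0.54 on slide 3. ABCB1, the P-glycoprotein gene, was outside the filter: it was well above background on no A2780 array and on 3 A2780cis arrays, with a log2 signal of 3.23 on both slide 1 arrays and -4.13 on replicate 3.

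**Figure D3:**
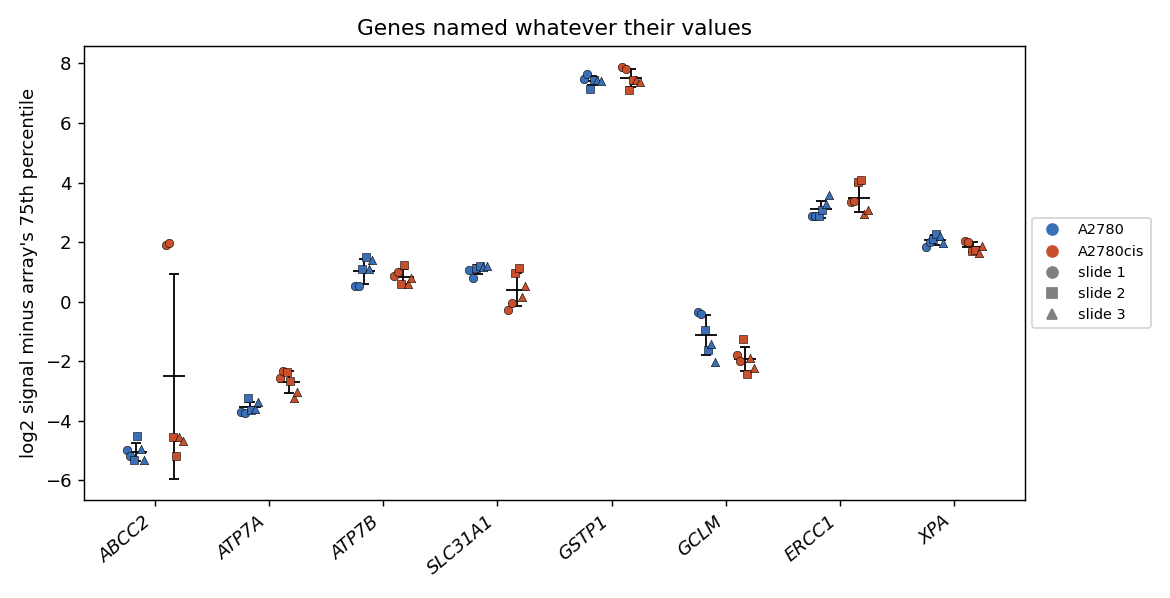
Log2 signal minus the array's 75th percentile for 8 of the genes named whatever their values, with each point 1 array, the long bar the mean of a line and the error bar its SD (n = 6). ABCC2 is at 1.90 and 1.96 on the slide 1 A2780cis arrays and below -4 on all others.

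In glutathione metabolism, which conjugates platinum, 7 of 30 genes rose and 0 fell (the same when adjusted over the list alone; camera adjusted p = 0.0747). Without slide 1 there were 5 and 2, and with slide as a block 10 and 2. MGST1 rose the most (5.29 ± 0.23), followed by GSTA4 (0.88 ± 0.17), GSTO1 (0.72 ± 0.19) and MGST3 (0.63 ± 0.19), and MGST3 lost its call with the replicate block (adjusted p = 0.0651). Without slide 1 GSTO1 (0.60, adjusted p = 0.102) and MGST3 (0.29, adjusted p = 0.252) lost their calls. MGST3 also lost it in 8 of the 12 fits with 1 array left out. GSTP1 was at 0.09 ± 0.16 (limma adjusted p = 0.79). GCLM, a subunit of the enzyme that starts glutathione synthesis, was at -0.81 ± 0.30 and did not pass (limma adjusted p = 0.0856), but passed with the replicate block (adjusted p = 0.0322). Of 10 metallothioneins, which bind metal ions, 8 rose and 0 fell (adjusted over the list alone, 9 and 0; camera adjusted p = 1.08e-04, or adjusted p = 0.959 with an estimated correlation). MT2A (2.30 ± 0.26), MT1G (1.69 ± 0.35), MT1X (1.62 ± 0.28) and MT1B (1.51 ± 0.29) rose the most. The median of the list was 2.29 on slide 1, 1.22 on slide 2 and 0.83 on slide 3. Of 23 NRF2 target genes 3 rose and 2 fell (the same when adjusted over the list alone; camera adjusted p = 0.889). PIR (1.08 ± 0.19) and SRXN1 (0.81 ± 0.23) rose, AKR1B10 was at least 4.66-fold higher in A2780cis but reversed under normexp background correction as planned, and AKR1C3 fell (-2.20 ± 0.21). SRXN1 lost its call in 8 of the fits with 1 array left out.

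DNA repair lists did not pass. In mismatch repair 2 of 16 genes rose and 2 fell (the same when adjusted over the list alone; camera adjusted p = 0.581). LIG1 (1.22 ± 0.24) and PCNA (0.76 ± 0.19) rose, and RFC3 (-1.05 ± 0.19) and MSH6 (-0.77 ± 0.16) fell. In nucleotide excision repair, which removes platinum adducts, 1 of 25 genes rose and 2 fell (adjusted over the list alone, 0 and 2; camera adjusted p = 0.986). UVSSA rose (0.57 ± 0.18), ERCC4 (-0.94 ± 0.24) and ERCC6 (-0.69 ± 0.18) fell, and ERCC1 (0.37 ± 0.23, limma adjusted p = 0.309) and XPA (-0.23 ± 0.14, limma adjusted p = 0.286) did not pass. Without slide 1 ERCC4 (-0.74, adjusted p = 0.134) and UVSSA (0.69, adjusted p = 0.0567) lost their calls, and UVSSA in 8 of the fits with 1 array left out. Of 30 Fanconi anaemia and homologous recombination genes 4 rose and 1 fell (the same when adjusted over the list alone; camera adjusted p = 0.509). These included RAD51B (1.98 ± 0.24), NBN (1.60 ± 0.33), UBE2T (0.65 ± 0.19) and MRE11 (-0.75 ± 0.22). UBE2T lost its call in 7 and MRE11 in 4 of the fits with 1 array left out. In translesion synthesis 2 of 13 genes rose, POLH (1.66 ± 0.34, and 0.64 by its other kept probe) and HLTF (1.09 ± 0.28), and RAD18 fell (-0.56 ± 0.17; adjusted over the list alone, 3 and 1; camera adjusted p = 0.734). RAD18 lost its call without slide 1 (-0.41, adjusted p = 0.204) and in 7 of the fits with 1 array left out.

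Of 29 p53 target genes 5 rose and 2 fell (the same when adjusted over the list alone; camera adjusted p = 0.911), with list medians of -0.61 on slide 1 and 0.32 and 0.31 on slides 2 and 3. FAS, a death receptor gene, rose (2.41 ± 0.59; 0.04 on slide 1) and so did FDXR (1.31 ± 0.18). SESN2 fell (-1.45 ± 0.16), as did TP53INP1 (-3.89 ± 1.27), which was at 0.61 on slide 1 and -6.79 and -5.50 on slides 2 and 3 and lost its call with the replicate block (adjusted p = 0.0523) and in 10 of the fits with 1 array left out. Among 28 genes of the BCL2 family and inhibitors of apoptosis 0 rose and 4 fell (adjusted over the list alone, 0 and 2; camera adjusted p = 0.734). This one-sided count was not kept with slide as a block (5 rose and 6 fell) or without slide 1 (7 rose and 4 fell). With slide as a block the 4 that fell in the fit kept their calls. Those that fell in the fit were BIRC7 (-1.46 ± 0.40), MCL1 (-0.63 ± 0.16), BAK1 (-0.51 ± 0.16) and BCL2 (-1.45 ± 0.46; -3.19 on slide 1), the last of which lost its call with the replicate block (adjusted p = 0.0634). Without slide 1 BAK1 (-0.46, adjusted p = 0.165) and BCL2 (-0.58, adjusted p = 0.36) lost their calls, as they did in 11 and 9 of the fits with 1 array left out.

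HLA class I antigen presentation fell in 14 of 20 genes, and 0 rose (adjusted over the list alone, 15 and 0; camera adjusted p = 2.66e-11). With an estimated correlation the list had p = 0.0307 and adjusted p = 0.959. The list median was -2.56 on slide 1, -1.44 on slide 2 and -1.55 on slide 3. The immunoproteasome gene PSMB9 (-7.18 ± 0.32), the peptide transporter gene TAP1 (-3.64 ± 0.41), HLA-B (-3.39 ± 0.43) and HLA-F (-3.39 ± 0.31) fell the most. Of 32 interferon-stimulated genes 12 fell and 4 rose (adjusted over the list alone, 13 and 6; camera adjusted p = 0.0701). BST2 (-7.12 ± 1.56, with -1.07 on slide 1), IFITM1 (-4.60 ± 0.63), IRF1 (-3.30 ± 0.41) and MX1 (-3.12 ± 0.41) fell the most. IFITM1 had a log2 signal of 3.29 and 3.13 on the slide 1 A2780cis arrays and at most 0.0085 on the other 4. Of 13 NF-kB targets and cytokines only CXCL1 passed, at least 1.40-fold lower in A2780cis (1 when adjusted over the list alone; camera adjusted p = 0.889).

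**Figure D4:**
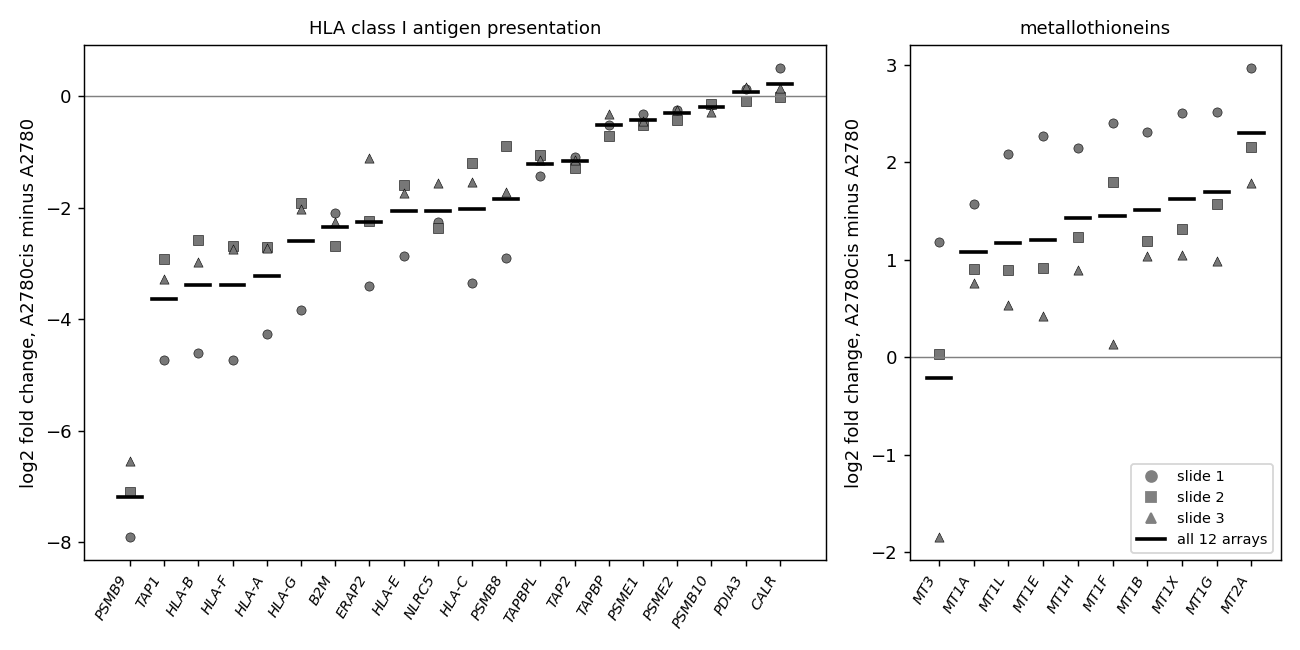
Log2 fold change, A2780cis minus A2780, of each tested gene of the HLA class I list (left) and of the metallothioneins (right), with grey points for the value within each slide and a bar for all 12 arrays. The list medians of slides 1, 2 and 3 are -2.56, -1.44 and -1.55 on the left and 2.29, 1.22 and 0.83 on the right.

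Of 29 cholesterol and fatty acid synthesis genes 10 rose and 2 fell (adjusted over the list alone, 16 and 3; camera adjusted p = 0.00548, or adjusted p = 0.959 with an estimated correlation). SC5D (3.63 ± 0.36), STARD4 (1.84 ± 0.40) and MSMO1 (1.498 ± 0.44) rose, and the desaturase gene FADS2 fell (-3.16 ± 0.21). MSMO1 lost its call in 8 of the fits with 1 array left out. The list median was 1.16 on slide 1, 0.03 on slide 2 and 0.82 on slide 3, and the list did not pass without slide 1 (camera adjusted p = 0.087). In hypoxia and glycolysis 5 of 32 genes rose and 2 fell (the same when adjusted over the list alone; camera adjusted p = 0.693), with medians of 0.77, -0.09 and -0.53 on slides 1 to 3. NDRG1 (3.78 ± 0.27), CA12 (2.65 ± 0.28) and PFKP (2.59 ± 0.61) rose, and ENO2 fell (-4.89 ± 1.12; -0.93 on slide 1) and was well above background on 2 of 6 A2780cis arrays. Among 25 genes of ATF4 and the unfolded protein response 2 rose and 2 fell (the same when adjusted over the list alone; camera adjusted p = 0.134), with a median of -1.04 on slide 1 against 0.06 and -0.08 on slides 2 and 3. CRELD2 (1.23 ± 0.25) and SDF2L1 (0.84 ± 0.22, and 0.83 with an adjusted p of 0.0721 without slide 1) rose, and PHGDH, of serine synthesis, fell (-1.33 ± 0.15) along with SESN2. Of 48 oxidative phosphorylation genes 2 rose, UQCRB (0.69 ± 0.16) and NDUFC1 (0.58 ± 0.18, and 0.39 with an adjusted p of 0.208 without slide 1), and 0 fell (adjusted over the list alone, 1 and 0; camera adjusted p = 0.911). Without slide 1 there were 1 and 3, with slide as a block 6 and 4, and NDUFC1 lost its call in 7 of the fits with 1 array left out. Of 47 cytosolic ribosomal protein genes 0 passed limma, also when adjusted over the list alone, with 2 at an unadjusted p under 0.05 (camera adjusted p = 0.889), and their median was 0.02.

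Of 33 G2/M genes 4 rose and 0 fell (the same when adjusted over the list alone; camera adjusted p = 0.0701), and the list passed as higher with the replicate block (camera adjusted p = 0.00635) and without slide 1 (camera adjusted p = 0.018), but not with an estimated correlation (camera adjusted p = 0.959). ASPM (1.25 ± 0.20), KIF20A (1.09 ± 0.33), ANLN (0.96 ± 0.22) and PTTG1 (0.90 ± 0.26) rose. Without slide 1 KIF20A (1.12, adjusted p = 0.112) and PTTG1 (0.82, adjusted p = 0.0572) lost their calls at changes close to those of the fit, as they did in 8 and 7 of the fits with 1 array left out. Among 31 G1/S genes TK1 rose (0.93 ± 0.30, and 0.63 with an adjusted p of 0.303 without slide 1) and CDC25A fell (-0.84 ± 0.17; adjusted over the list alone, 0 and 1; camera adjusted p = 0.509). TK1 lost its call in 8 of the fits with 1 array left out.

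Markers of cell state moved in both directions. Of 18 mesenchymal markers 5 rose and 4 fell (adjusted over the list alone, 6 and 4; camera adjusted p = 0.852). TWIST2 (6.91 ± 0.55) and TCF4 (2.82 ± 0.20) rose, and POSTN (-5.55 ± 0.66) and TWIST1 (-6.03 ± 1.497) fell, and TWIST1 was at -0.62 on slide 1 against -8.73 on each of slides 2 and 3. TWIST2 was well above background on 4 of 6 A2780 arrays and POSTN on 2 of 6 A2780cis arrays. Of 17 epithelial markers 1 rose, the keratin gene KRT18 (2.58 ± 0.24), and 3 fell, ELF3 (-3.28 ± 0.52, well above background on 3 of 6 A2780cis arrays), CLDN7 (-1.93 ± 0.25) and OCLN (-1.10 ± 0.15; adjusted over the list alone, 1 and 4; camera adjusted p = 0.581). Among 35 collagens, matrix and integrin genes 9 rose and 4 fell (adjusted over the list alone, 9 and 6; camera adjusted p = 0.677). COL3A1 rose (2.54 ± 0.30), as did COL12A1 (7.35 ± 1.94; 0.32 on slide 1), which was well above background on 1 of 6 A2780 arrays. ITGA1 (-4.89 ± 0.64) and COL4A6 (-4.27 ± 1.16; -0.27 on slide 1) fell and were well above background on 3 and 2 of 6 A2780cis arrays. Of 16 stem cell and progenitor markers 3 rose and 4 fell (adjusted over the list alone, 3 and 5; camera adjusted p = 0.509). The pluripotency factor gene SOX2 (-5.74 ± 0.14) and LIN28B (-1.83 ± 0.53) fell, LIN28A was at least 14.2-fold lower, and ALDH1A1 rose (3.54 ± 0.37). LIN28B lost its call in 6 of the fits with 1 array left out.

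Of 23 HOX genes 5 rose and 6 fell (adjusted over the list alone, 5 and 7; camera adjusted p = 0.509). HOXB13 rose (4.81 ± 0.24). HOXC12 was at least 16.9-fold higher in A2780cis on average, with a log2 signal of 1.96 and 2.09 on the slide 1 A2780cis arrays and -3.94 or less on the other 4. HOXB9 (-6.33 ± 0.96; -2.47 on slide 1) and HOXB6 (-4.21 ± 0.95; -0.73 on slide 1) fell. Of 36 Wnt pathway genes 11 rose and 4 fell (adjusted over the list alone, 12 and 4; camera adjusted p = 0.0747, 0.0189 without slide 1 and 0.959 with an estimated correlation). FZD1 (2.67 ± 0.23, and 0.51 by its other kept probe) and WNT3 (2.15 ± 0.31) rose, and so did the inhibitor genes DKK2 (4.47 ± 1.34; 0.03 on slide 1) and SFRP1 (3.08 ± 0.82; 0.01 on slide 1). DKK2 lost its call in 10 of the fits with 1 array left out, and SFRP1 was well above background on 4 of 6 A2780 arrays. In the TGF-beta and BMP pathway 9 of 37 genes rose and 2 fell (adjusted over the list alone, 10 and 2; camera adjusted p = 0.467). Besides INHBA, TGFB3 rose (1.66 ± 0.24), and TGFB2 fell (-4.13 ± 0.44), well above background on 2 of 6 A2780cis arrays. Of 35 growth factor receptors and ligands 7 rose and 7 fell (adjusted over the list alone, 10 and 7; camera adjusted p = 0.911). VEGFC (6.58 ± 1.04, with 2.69 on slide 1) and FGF1 (4.38 ± 0.85) rose. FGF1 was well above background on 1 of 6 A2780 arrays. Its log2 signal was -5.35 and -5.86 on the slide 1 A2780cis arrays and at least -1.73 on the other 4. FGF18 (-8.23 ± 0.24) and AREG (-5.64 ± 0.41, well above background on 4 of 6 A2780cis arrays) fell. Of 10 cancer-testis antigens PAGE2 rose (0.70 ± 0.19), and MAGEA8 (-1.04 ± 0.33) and MAGEB2 (-0.77 ± 0.17) fell (the same when adjusted over the list alone; camera adjusted p = 0.693). PAGE2 reversed under normexp as planned (-0.23). MAGEA8 reversed under repaired normexp (0.0262), lost its call in 10 of the fits with 1 array left out, and was well above background on 2 of 6 A2780cis arrays.

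Markers of other cell types showed no joint shift that passed. Of 7 fibroblast markers COL3A1 rose and PDGFRA fell (-3.92 ± 1.28; 0.66 on slide 1), the same when adjusted over the list alone (camera adjusted p = 0.889), and PDGFRA lost its call with the replicate block (adjusted p = 0.0522) and in 10 of the fits with 1 array left out. Of 8 leukocyte markers CD68 rose (2.89 ± 0.49) and LCP1 fell (-2.81 ± 0.44), the same when adjusted over the list alone (camera adjusted p = 0.929). Of 5 endothelial markers 0 passed limma, also when adjusted over the list alone, with 1 at an unadjusted p under 0.05 (camera adjusted p = 0.528). Of 5 keratinocyte and squamous markers SFN (1.98 ± 0.63) and TP63 (1.45 ± 0.24) rose, the same when adjusted over the list alone (camera adjusted p = 0.509). SFN was at 3.96 on slide 1 and lost its call without slide 1 (0.99, adjusted p = 0.189) and in 7 of the fits with 1 array left out.

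**Figure D5:**
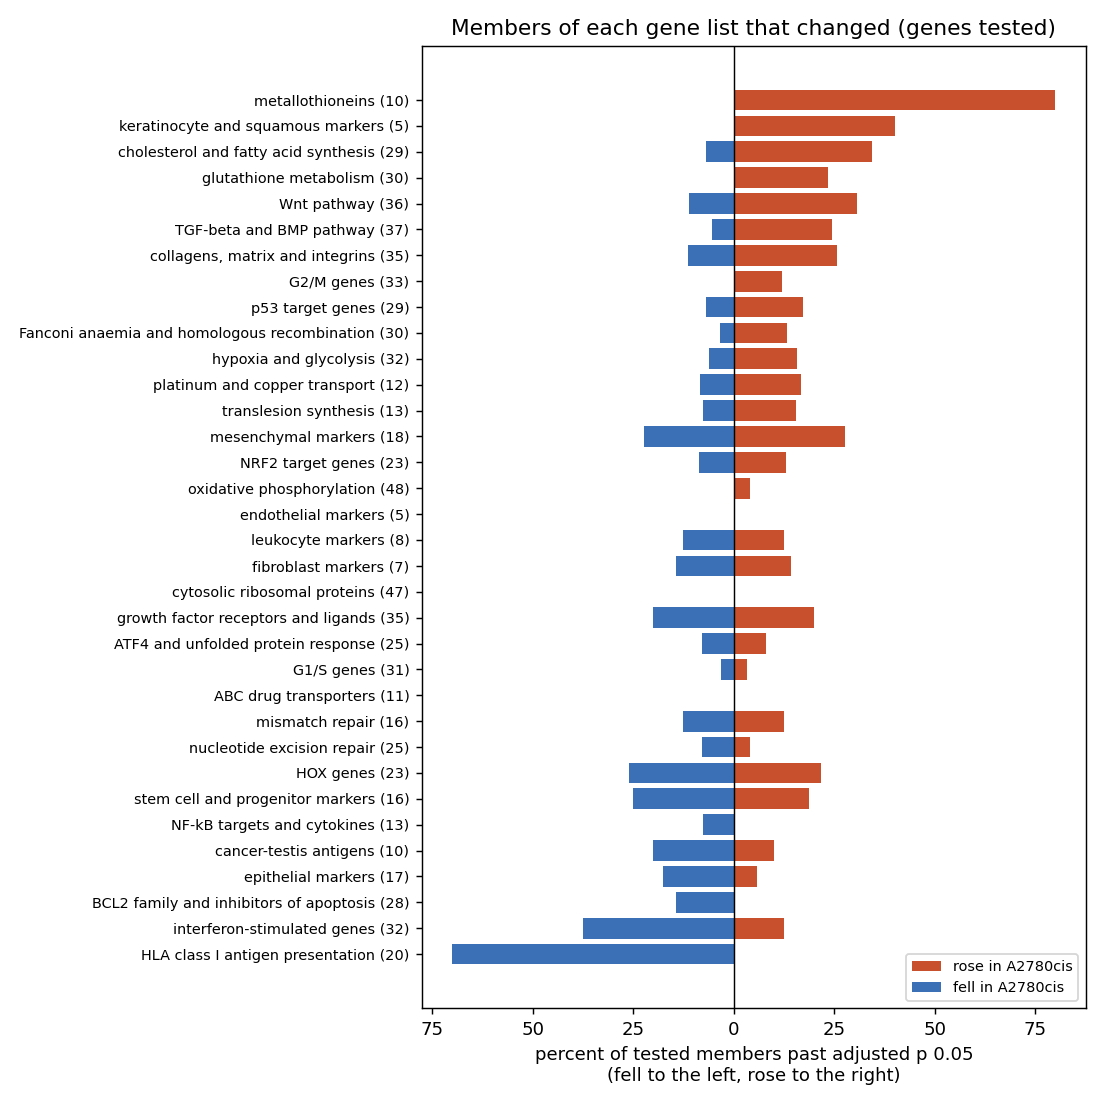
Percent of tested members of each of the 34 gene lists that rose (right of 0) or fell (left of 0) in A2780cis past the adjusted p of 0.05, with the number of genes tested in brackets. HLA class I antigen presentation has 14 of 20 genes to the left and metallothioneins 8 of 10 to the right.

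Of the 34 lists 3 passed with the preset correlation and 0 with an estimated correlation, with which 1 had an unadjusted camera p under 0.05. The direction of the camera test differed in sign from the median or the mean in nucleotide excision repair, platinum and copper transport, ABC drug transporters, BCL2 family, hypoxia and glycolysis, growth factor receptors and ligands, and oxidative phosphorylation, none of which passed.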

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

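The tests of a shared slide effect, of admixed A2780 material, of swapped labels and of 1 wrong label, the tests of cross-hybridisation and of interferon signalling, and the ranking of single lists over splits were chosen after the results they bear on were seen.

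The line difference differed between slides in 6257 of 22127 genes (limma interaction), with 5900 for slide 1 against slide 2, 5596 for slide 1 against slide 3 and 584 for slide 2 against slide 3. These counts rest on the spread between arrays of a line on the same slide and may be too high. Across genes, which are not independent replicates, the line differences of slides 2 and 3 correlated at 0.885, those of slides 1 and 2 at 0.479 and those of slides 1 and 3 at 0.471. The separation lay in A2780cis, where 6428 genes (29.1%) were at least 2-fold apart between slide 1 and slides 2 and 3, against 2354 (10.6%) in A2780. A slide effect shared by both lines would move A2780 as well, but over 6423 of those genes the A2780 difference was a median 0.218 of the A2780cis one (95% bootstrap interval 0.206 to 0.229), under the bound of 0.25 by a narrow margin, so a smaller shared part is not excluded. A2780 material mixed into the slide 1 A2780cis samples would place values between the lines, whereas 34.9% lay more than 1 log2 unit outside that interval. Swapped labels need slide 1 A2780 arrays out of place, yet these correlated better with A2780 than with A2780cis of slides 2 and 3, by at least 0.0788. With 1 wrong label the other slide 1 A2780cis array would resemble the rest of its line, yet neither correlated above 0.908 with A2780cis of slides 2 and 3, against at least 0.9592 between slide 1 and the other slides in A2780. With A2780 they correlated at 0.8959 to 0.9128, also under that value. Wrong labels on both arrays, another subline or passage of A2780cis, and a fault in handling those samples stay open, and no biological explanation was tested.

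In data outside the filter, 363 probes (196 named genes) were well above background on both slide 1 A2780cis arrays and on none of the other 10 arrays. The like count was 128 probes for the slide 1 A2780 arrays, 72 for the 4 A2780cis arrays and 0 for the 4 A2780 arrays of slides 2 and 3. These counts compare sets of 2 and of 4 arrays and were not tested.

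HLA class I antigen presentation genes were lower in A2780cis on every slide. Loss of the stretch of genome that holds the HLA genes would lower their neighbours, but 95 neighbours of no list had a median of 0.04 (0.0382, 95% bootstrap interval -0.0986 to 0.119) against -2.59 for the 11 list members of that region. Signal shared between near-identical HLA probes cannot account for the 14 members not named HLA, whose median was -1.19 (95% bootstrap interval -2.25 to -0.357). Of these 14, 8 fell and 0 rose past the threshold. Whether the members named HLA share signal among themselves is not addressed by this test. Lower interferon signalling may contribute, and the interferon-stimulated list was lower, with a camera adjusted p of 0.0701 that decided neither way and that passed under some settings and not under others. For the HLA class I list 1 of 100 splits, the real one, gave a camera p as small as 7.82e-13. In 8 of 100 splits some list reached that value. The interferon-stimulated list reached its own camera p of 0.0103 in 18 of 100 splits.

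The 12 arrays were also divided in 100 ways into 6 and 6, the real division included. The real one gave 4263 genes past the threshold and was the only 1 of 100 with as many, the highest of the others being 1591. With the 2-fold limit it gave 2706 genes, again the only 1 of 100, with 845 the highest of the others. The other divisions mix the lines, which puts the line difference into their error, and their median was 0 genes for both counts. The 2 arrays of a line on a slide also tended to be more alike than arrays across slides, so arrays cannot be freely exchanged. The divisions therefore cannot exclude chance for either count. The 1591 genes came from the division that put A2780 replicates 1, 2, 5 and 6 with A2780cis replicates 1 and 2, with all 4 slide 1 arrays and both slide 3 A2780 arrays on the same side, and whether line or slide gave these calls was not tested. Within slides the lines gave 12580, 3393 and 5845 genes. Chance is also not excluded for the number of lists, since 82 of 100 divisions gave at least the real 3 (highest other 14). The same holds for segments, since 48 of 100 gave at least the real 24 (highest other 50). Metallothioneins reached their camera p in 10 of 100 divisions, cholesterol and fatty acid synthesis in 25 and G2/M genes in 56. Compared with the 6 other divisions that parted all 6 numbered pairs, the real one stood out by genes (highest other 0 by limma) and did not by lists (8) or segments (48).

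Among 272 groups of 6 values checked, 4 held a value far from the other 5, by the gap to the nearest over the whole range. Chance gives 1 in 20 for independent values. Arrays of a line on a slide tended to be alike, so the 4 cannot be set against that rate. In A2780 this ratio was 0.785 for COL12A1 and 0.646 for INHBA, both in replicate 6, and 0.654 for SLC31A1 in replicate 2. The median signal of negative controls in A2780cis replicate 3, 42 against 24 to 28 in the other A2780cis arrays, had a ratio of 0.778.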

How the results depend on the processing

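The alternatives without slide 1, with array pairs averaged (3 against 3) and with repaired normexp were chosen after the data were seen. The fit called 4263 genes, 2706 of them by 2-fold, 3 lists and 24 segments. Gene counts stayed within 1.5 times under quantile normalization (4188), median scaling (3954), the authors' values, both filters and without slide 1 (5730). The fit had more that rose than fell (2304 and 1959), and this turned under median scaling (1826 and 2128) and was about even without slide 1 (2871 and 2859) and with array pairs averaged (537 and 556). Of the 4263 genes, 3992 were also called with quantile normalization, 3711 with median scaling and 3513 without slide 1. With the replicate block 6181 genes passed, 4107 of them among the 4263; of the named genes and lists it changed only the calls given beside them. Slide as a block gave 7176 genes and array weights 7485, with 6 lists. Within slide 1 there were 12580 genes, 4960 by 2-fold, 8 lists and 47 segments (19 higher, 28 lower), and lists numbered 5 within slide 2 and 7 within slide 3. With array pairs averaged, 1093 genes passed, all by 2-fold. Fewer samples enter that fit, and the arrays of a line on a slide are no longer counted as separate cultures. Which of these lowered the count was not tested.

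Normexp as planned gave 999 genes (440 rose, 559 fell), 969 by 2-fold, and 11 lists, and put the median of all genes at -0.15. A2780 replicate 5 held 9 spots with a local background over 3 times its median of 17, the highest 672104, and its normexp values correlated at 0.641 with its processed signal. With those backgrounds replaced the correlation was 0.978, and normexp gave 3710 genes, 1564 by 2-fold, and 5 lists. AKR1B10 (-0.0316) and PAGE2 (-0.23) reversed under normexp as planned, and MAGEA8 (0.0262) under the repaired one. Mean log2 signals of these genes were at most -4.16 in either line.

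Within slide 1 TP53INP1 (0.61), PDGFRA (0.66) and ATP7B (0.41) reversed, and the p53 list was lower (camera adjusted p = 0.00204). The hypoxia list was lower within slide 3 (camera adjusted p = 0.0324). The cholesterol list had a camera direction of lower within slide 2 but showed no shift there (camera adjusted p = 0.961, median 0.03). The causes were not tested. Lists numbered 5 with no filter and 5 when all 12 arrays had to be above background. Segments, 14 of them higher and 10 lower in the fit, numbered 43 with no filter (9 higher, 34 lower), 30 under normexp as planned (22 and 8), 21 without slide 1 (8 and 13), 13 at 20 Mb (6 and 7) and 2 with an estimated correlation, which left 0 lists (1 at an unadjusted camera p under 0.05). Leaving out 1 array gave 3546 to 4524 genes, 2435 to 3013 by 2-fold, 3 to 6 lists and 19 to 29 segments. There were 5 lists without A2780 replicate 1 or 2 or A2780cis replicate 3, and 6 without A2780cis replicate 4.

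Of 131 named genes tested 124 passed. Of these, 48 kept the call under every setting that tested them, leaving aside those within a slide. The filter requiring all 12 arrays tested only 93 of the 131, so some of the 48 may not have met it. The call was lost by 69 with array pairs averaged, 32 within slide 2 and 56 under normexp as planned, besides the 2 that reversed there and did not pass either. Without slide 1 it was lost by 14, ERCC4, UVSSA, RAD18, ATP7A, GSTO1, MGST3, BCL2, BAK1, TK1, KIF20A, PTTG1, SDF2L1, NDUFC1 and SFN (adjusted p 0.0567 to 0.36). With single arrays left out 19 lost the call, each without 4 to 11 of the arrays in turn, at an adjusted p of up to 0.105. They were BAK1 (11 arrays), DKK2, MAGEA8, PDGFRA and TP53INP1 (10 each), BCL2 (9), KIF20A, MGST3, MSMO1, SRXN1, TK1 and UVSSA (8 each), NDUFC1, PTTG1, RAD18, SFN and UBE2T (7 each), LIN28B (6) and MRE11 (4). SLC31A1 passed without A2780cis replicate 3 (0.0378) or 4 (0.0224) and GCLM without A2780 replicate 6 (0.0306). The interferon list passed in 5 of the fits with an array left out (lowest adjusted p 0.0321). It also passed as lower with no filter (0.0027), with all 12 arrays above background (0.0116), under normexp as planned (0.0389) and repaired (0.0123), and within slides 1 (0.0306) and 3 (0.0393), but not without slide 1 (0.14) or with an estimated correlation (0.959). Low signal limits the filter: 69.7% of probes passed it.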

Other observations

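The genes and segments named here were picked after their values were seen, and the copy number reading was changed after its result was seen, as stated beside it.

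Within A2780cis, some genes differed widely between slide 1 and slides 2 and 3. VAV3, a guanine nucleotide exchange factor gene, had a log2 signal of 4.86 in A2780cis on slide 1 and was at least 1646-fold lower on slides 2 and 3, where it was not well above background. TMEM30B (at least 1080-fold) and EYA4 (at least 235-fold), a developmental transcription regulator gene, had the same pattern. In the other direction, SEC11C was at least 894-fold, PGAP4 at least 773-fold, the methyl-CpG binding gene MBD2 at least 581-fold, MEOX2 at least 461-fold and RCOR1 at least 442-fold lower in A2780cis on slide 1 than on slides 2 and 3. S100A6 had a log2 signal of 5.78 in A2780cis on slide 1 against -4.69 and -5.59 on slides 2 and 3, and the collagenase gene MMP1 -5.16 against 6.41 and 5.93. Limma's interaction of slide and line passed for each of these genes, but passing it was a condition of their choice and adds no evidence.

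Outside the filter, LGALS3 (galectin-3) had a mean log2 signal of 1.14 on the slide 1 A2780cis arrays and -7.30 over the other 10 arrays. The noncoding RNAs MIR100HG (1.33 against -7.96) and HOTAIR (0.11 against -7.68) and the genes PLAC8 (0.38 against -7.22) and SORBS2 (-0.81 against -8.45) had the same pattern.

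Of 290 chromosome segments, 14 were higher and 10 lower in A2780cis (camera), and with an estimated correlation 0 were higher and 2 lower. From TPD52 to NBN 13 of 22 genes rose and 0 fell (median 1.09; 0.28, 1.58 and 1.13 on slides 1 to 3; camera adjusted p = 6.72e-08, or adjusted p = 0.676 with an estimated correlation), CA2, CA13, FABP5 and RIPK2 among them. From GNAI1 to SRI, with CD36 and SEMA3C, 10 of 17 rose and 1 fell (median 1.36; camera adjusted p = 0.00231, or adjusted p = 0.641 with an estimated correlation). From PRMT3 to METTL15 10 of 17 genes fell and 0 rose, including ANO3, BDNF and LGR4 (median -1.20; camera adjusted p = 6.72e-08, or adjusted p = 0.0156 with an estimated correlation). From ADGRL2 to ZNF326 17 of 38 fell and 2 rose, with GBP1 and LRRC8D among those that fell (median -0.49; camera adjusted p = 5.34e-05, or adjusted p = 0.0301 with an estimated correlation). From ZNF626 to URI1, a cluster of related zinc finger genes, 13 of 22 fell and 0 rose (median -1.24; camera adjusted p = 2.45e-07, or adjusted p = 0.641 with an estimated correlation).

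Neighbouring genes that shift together may reflect copy number differences between the lines, a hypothesis. Over all genes 2 to 5 Mb apart the correlation of log2 fold changes across genes was 0.014 (jackknife SE 0.00581), above the highest of 100 shuffles (0.00457) and under the bound of 0.05 set in advance for its absence. By that bound the planned test went against copy number differences across the genome. The reading was changed to undecided after the value was seen, because the test pools 290 segments and dilutes a shift in a few. The 24 segments that passed cannot settle this, because chance is not excluded for their number. Copy number and shared regulation cannot be told apart without DNA. Placement on the array does not account for the pattern, since probes of adjacent genes lay as far apart as random pairs (ratio of medians 1). The number of segments was reached by 48 of 100 divisions of the arrays, so chance is not excluded for it. These divisions mix lines and slides, so they cannot show how many segments chance alone would give.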
